A study of Mus musculus with 16 samples.

How the data were processed

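Bulk RNA-seq of mouse bone marrow hematopoietic stem cells (HSCs) was analysed in 16 libraries from 6 groups. The cells carried either an intact Selp gene (WT) or a knockout of it (KO). They were collected fresh, after culture with vehicle, or after culture with the P-selectin ligand PSGL-1. Library numbers in the labels ran to 18, and numbers outside the 16 libraries were not analysed here.

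The values were raw read counts per gene symbol, one column per library, as deposited by the authors. Per the labels' protocols, RNA was isolated with a micro-scale column kit and libraries were made with the SMART Ultra-Low Input kit, which amplifies full-length cDNA from small amounts of RNA. STAR 2.7.5c, featureCounts, MultiQC 1.10, DESeq2 and the genome build mm10 are named per the submitters' processing notes. The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of near-identical gene copies could therefore have been split or lost. The libraries carry no molecular identifiers in the sources used here, so detection floors cover counting error only; the 1 interval given covers the spread over list members.

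The file held 25239 genes, of which 14124 passed edgeR's filterByExpr by group and were tested. Library totals ran from 12590539 to 24690824 counts, so that a count of 3, used as the detection floor per library, corresponded to 0.122 to 0.238 CPM, the standard scaling of counts to the library total. Totals were scaled by the trimmed mean of M values (TMM). One edgeR quasi-likelihood model with robust estimation was fitted to all 16 libraries with one mean per group, since some groups held 2 libraries. Changed genes had a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The common biological coefficient of variation was 0.977. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM ± SD over the libraries of a group. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

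The 8 comparisons, 34 gene lists, main tests and the rule for named genes were fixed before the data were examined. Outside that plan were the permutation test of Selp and Selplg and the counts near Selp at an unadjusted p under 0.01. So was the adjustment over a list alone, which was not corrected over lists or comparisons. Each list with at least 5 tested genes, 30 in all, was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Each was tested again with an estimated correlation and with fry, which asks whether the members of a list move on balance one way. Named genes were Selp and Selplg in each comparison. Next came up to 10 genes with the largest positive and up to 10 with the largest negative change among changed genes with a mean of at least 5 CPM in 1 group, no overlap between the libraries of both groups, and a regular gene symbol. From each list past the threshold the 4 members with the smallest adjusted p in its direction were taken, and from other lists up to 2 changed members. Genes outside this rule are said to be chosen after their values were seen. Single results of some genes are not reported here, though these genes stay in all fits, counts and lists. A fold against a group with 0 counts in each library is given as a lower bound from the floor. Single-gene levels of Selp and Selplg over both genotypes were compared by an exact two-sided permutation test. Coordinates come from the RefSeq annotation of GRCm38.p6, the assembly also named mm10. Of the 25239 symbols, 25145 matched it, 105 of them through a synonym.

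Alternatives were DESeq2, another scaling (RLE size factors), no filter and a stricter filter, a 2-fold minimum, fits of the groups compared alone, each library left out in turn, and the replicate numbers as a block. Added after the data were seen were limma voom with library quality weights, fits without the sparse library WT PSGL-1 replicate 1, the difference of the culture response between genotypes, and the KO against WT difference averaged over the 3 conditions. Libraries of a group were counted as separate samples because the labels list them so. No pair agreed within sampling noise, so none was taken for 1 library listed again, though this does not show that they are biological replicates. The smallest chi-square per degree of freedom within a group was 60.19. The labels do not say whether replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical.

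The fitting steps were tested on simulated counts in which 50 genes of each fold size were changed among 14124. The changed genes had a mean of at least 5 CPM. Apart from these changes all simulated libraries shared 1 mean profile, so none was sparse like WT PSGL-1 replicate 1. For fresh KO against WT, 2% of the 2-fold, 30% of the 4-fold, 46% of the 8-fold and 56% of the 16-fold changes were recovered. For vehicle KO against WT these shares were 2%, 28%, 58% and 68%. For PSGL-1 against vehicle they were 0%, 26%, 48% and 48% in WT and 8%, 34%, 56% and 58% in KO. For vehicle against fresh they were 10%, 30%, 56% and 60% in WT and 4%, 26%, 50% and 58% in KO. False calls numbered 1 to 5 per comparison.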

Results

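HSCs of mice aged 4 to 6 months were profiled by RNA-seq to ask how P-selectin, the adhesion receptor encoded by Selp, and its ligand PSGL-1 affect these cells. Fresh cells gave 3 WT and 2 KO libraries, vehicle cultures 3 and 3, and cultures with PSGL-1 at 125 ng/mL for 24 hours 2 and 3. The culture medium contained fetal calf serum, stem cell factor, interleukin-11 and Flt-3 ligand. The duration of vehicle culture is not given in the sources used here. Library totals lay between 12590539 and 24690824 counts.

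The library WT PSGL-1 replicate 1 stood apart from the others. It had 9035 detected genes against 11101 to 13480 in the other 15 libraries, at a total of 17797833 counts. In it, 5165 of the 14124 tested genes had 0 counts. It was separated from the rest by the first principal component, which held 27.7% of the variance. Fresh libraries lay on the negative side of the second component (13.9%) and all cultured libraries but this one on the positive side. In the library KO fresh replicate 1, the 10 most abundant genes took 5.41% of the counts and the ribosomal RNA precursor Rn45s 1.59%.

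**Figure D1:**
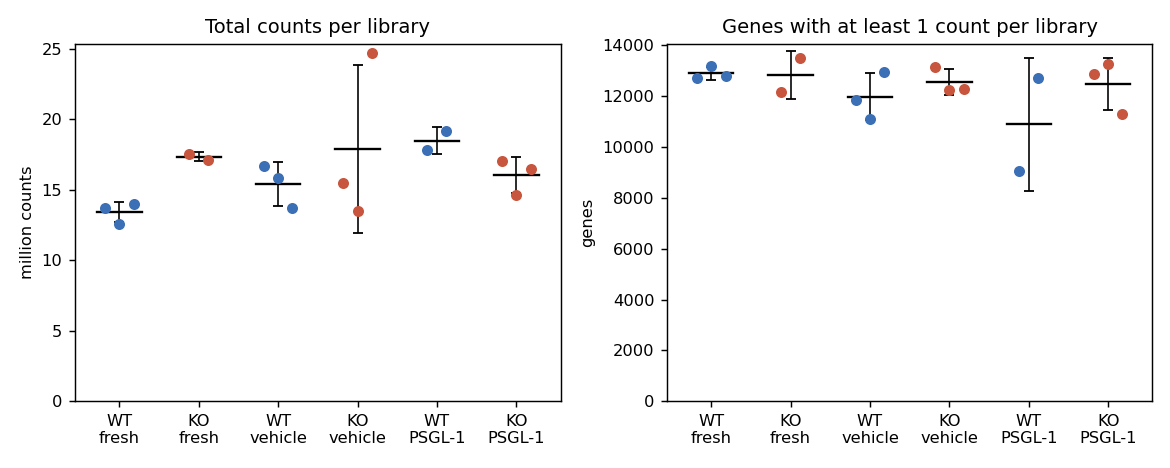
Total counts (left) and genes with at least 1 count (right) per library, by group. Points are libraries, black lines are means and bars are 1 SD; the lowest point on the right is WT PSGL-1 replicate 1 with 9035 genes.

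Markers of mature B, T and NK cells were low. The T cell gene Cd3e and the hemoglobin gene Hba-a1 had 0 counts in each of the 16 libraries, and Cd79a, a B cell gene, averaged 0 CPM in KO and 0.155 ± 0.291 CPM in WT (SD, n = 8 each). Cd79b, another B cell gene, had counts in each library, at 29.1 ± 15.8 CPM in KO and 39.9 ± 16.2 in WT. Summed B and plasma cell markers reached 55.4 ± 11.5 CPM in fresh WT and 51.5 ± 9.28 CPM in fresh KO. Of these sums, Cd79b gave 49.9 ± 10.2 and 46.1 ± 8.4 CPM. Summed T and NK cell markers reached 32.3 ± 16.3 and 26.4 ± 15.8 CPM there. Each of these lists had 4 tested genes, none of which passed edgeR's test in any comparison. Other summed markers were higher. In fresh WT and KO they reached 6430 ± 438 and 6700 ± 930 CPM for megakaryocytes and platelets, 3120 ± 281 and 2590 ± 655 for erythroid cells, 2140 ± 143 and 2570 ± 118 for granulocytes and monocytes, and 322 ± 26.4 and 303 ± 29.5 for endothelial and stromal cells. After vehicle the erythroid sums were 1580 ± 84.3 and 1150 ± 66.5 CPM and the endothelial and stromal sums 134 ± 67.4 and 143 ± 26. The neutrophil granule gene Mpo was uneven, with 0 counts in 7 of 8 KO and 3 of 8 WT libraries. Xist was detected in each library, at 240 ± 45.0 CPM in KO and 337 ± 124 CPM in WT, and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 counts throughout. None of the 13 listed genes encoded by mitochondrial DNA was in the count table.

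Selp, on chromosome 1 from 164115264 to 164150026, was low in all KO libraries. It averaged 5.08 ± 4.48 CPM in KO, with a range of 0 to 12.4, and 94.1 ± 60.0 CPM in WT, with a range of 16.8 to 183 (SD, n = 8 each). Each KO library lay below each WT library. The exact permutation test, which was not among the tests fixed beforehand, gave p = 0.000155, the smallest value it can give. It gave 0.00031 after adjustment over Selp and Selplg. Within conditions, Selp was at 1.17 ± 1.65 CPM in fresh KO and 67.7 ± 51.1 in fresh WT, at 7.51 ± 4.25 and 75.2 ± 58.0 after vehicle, and at 5.26 ± 5.16 and 162 ± 29.1 after PSGL-1. In edgeR the log2 differences were −5.86 (SE 1.85), −3.36 (1.36) and −4.95 (1.51), with adjusted p of 1, 1 and 0.765. DESeq2 gave −5.89 in fresh cells (adjusted p = 0.0112) and −4.95 after PSGL-1 (0.0292), while after vehicle Selp did not pass (0.557). Without WT PSGL-1 replicate 2 the edgeR value after PSGL-1 was −4.71 with an adjusted p of 0.043.

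Selplg, which encodes PSGL-1 itself, lies on chromosome 5 from 113817798 to 113832528. It was expressed at 323 ± 74.8 CPM in KO and 307 ± 75.6 CPM in WT (n = 8 each; exact permutation p = 0.664). It passed no edgeR test between genotypes, with culture or with PSGL-1.

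**Figure D2:**
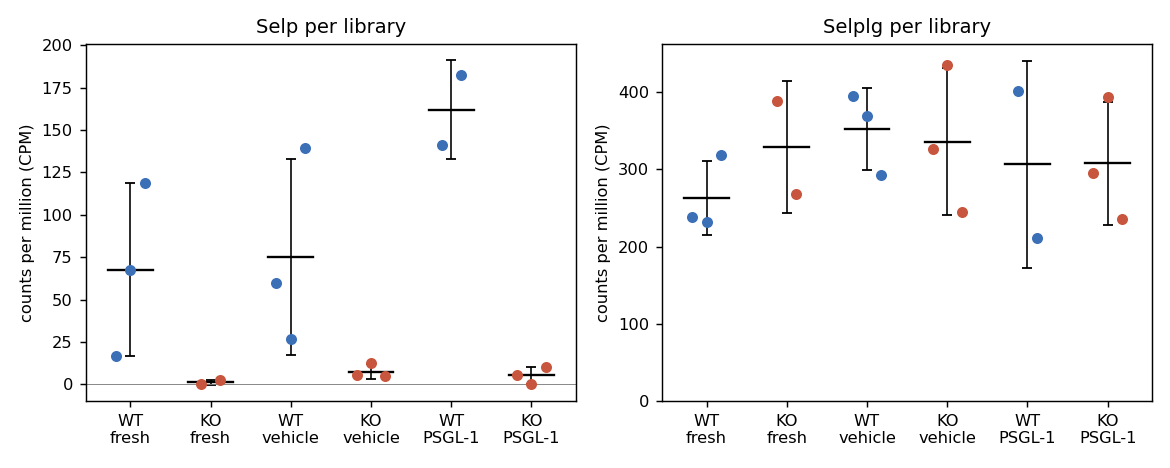
Selp (left) and Selplg (right) in CPM for each library, by group. Points are libraries, black lines are means and bars are 1 SD; Selp lies between 0 and 12.4 CPM in KO and between 16.8 and 183 CPM in WT.

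In fresh cells, genes of the cell cycle lay lower in KO than in WT. Of 44 tested genes of DNA replication and S phase, 39 had a log2 fold change below 0, with a median of −0.49. Of 45 mitosis genes, 38 were below 0, with a median of −0.50. The S phase median was −0.31 without KO fresh replicate 1, and the mitosis median was −1.17 without KO fresh replicate 2. Top2a, the topoisomerase of dividing cells, was at 115 ± 17.1 CPM in KO (n = 2) and 247 ± 25.7 CPM in WT (n = 3). Tyms, needed for thymidine synthesis, was at 72.4 ± 17.8 and 169 ± 35.9 CPM. Both lists fell in camera at the preset correlation (adjusted p = 1.42e-13 and 2.21e-13). With an estimated correlation their adjusted p were 0.23 and 0.25, and with fry 0.216 and 0.362. No member passed edgeR's test over all genes. Adjustment over the list alone is an easier threshold, not corrected over the lists or comparisons. By it 2 S phase genes were lower, Tyms and Pole, and 4 mitosis genes, Top2a, Kif11, Cenpe and Mki67.

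Genes known to be higher in aged HSCs lay higher in fresh KO cells. Of 46 tested members 42 were above 0, with a median log2 fold change of 0.82 (camera adjusted p = 3.41e-07; adjusted p = 0.25 with an estimated correlation). Clu, which encodes the secreted chaperone clusterin, was at 180 ± 70.4 CPM in KO and 41.4 ± 11 in WT. Its log2 difference was 2.15 (SE 0.39), with an edgeR adjusted p of 0.181 over all genes and 0.00236 adjusted over the list alone, the 1 member to pass there. Vwf, a platelet adhesion protein of platelet-biased HSCs, was at 311 ± 90.4 and 191 ± 73.2 CPM. Selp is itself a member of this list. Without KO fresh replicate 2 the list's median was 0.32 and its adjusted p 0.201.

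Of the 30 lists, 9 passed at the preset correlation in fresh cells, and none of them with an estimated correlation or fry. Immediate early genes had a median of 0.60 and a mean of 0.10 (adjusted p = 0.000978; 0.26 with an estimated correlation). HSC identity genes had a median of 0.22 (0.00359; 0.26), and genes of reactive oxygen and glutathione defence 0.25 (0.0297; 0.50). Cholesterol synthesis and uptake genes had a median of −0.38 (0.00124; 0.26), with 2 genes lower adjusted over the list alone, Fdps among them. Ribosome biogenesis and MYC target genes had a median of −0.18 (0.00412; 0.57). These calls other than cholesterol rested on single libraries. HSC identity and MYC targets lost theirs without KO fresh replicate 2 or WT fresh replicate 1 (highest adjusted p 0.191 and 0.504). Immediate early genes did so without KO fresh replicate 1 or WT fresh replicate 1 (0.0986), and glutathione defence without KO fresh replicate 1 or WT fresh replicate 3 (0.676). Cytosolic ribosomal protein genes had a median of 0.40 with 75 of 77 above 0 (adjusted p = 2.42e-12; 0.57 with an estimated correlation), which became −0.32 without KO fresh replicate 1 (adjusted p = 6.34e-14) and 0.88 without KO fresh replicate 2. Other medians also moved: HSC identity to 0.06 and 0.47 without WT fresh replicates 1 and 3, immediate early genes to 0.37 and 0.19 without KO fresh replicate 1 and WT fresh replicate 1, and cholesterol genes to −0.18 without KO fresh replicate 1. Glutathione defence moved to 0.03 and 0.39 without KO fresh replicates 1 and 2 and to 0.12 without WT fresh replicate 3.

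One single gene passed edgeR's test in fresh cells, Eno1b. It was at 75.2 ± 7.73 CPM in KO and 1.42 ± 0.0502 CPM in WT, a log2 difference of 5.78 (SE 0.40, adjusted p = 3.32e-06). Eno1b lies on chromosome 18 from 48045335 to 48048379 and closely resembles the enolase gene Eno1, so reads may be shared between them. At an unadjusted p under 0.05 there were 401 genes, with 706 expected by chance. DESeq2 called 99 genes, 35 higher and 64 lower, and limma with library weights 7. The edgeR count was 83 without KO fresh replicate 2, and 2 without WT fresh replicate 2.

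Culture changed the cells of both genotypes far more. Vehicle cultures differed from fresh cells in 231 genes in WT, 174 higher and 57 lower, and in 250 genes in KO, 174 higher and 76 lower. Both genotypes shared 103 higher and 40 lower genes, where independent lists would share 2.14 and 0.307, and none changed in opposite directions. Across 10676 genes the fold changes correlated with r = 0.548, and 71.4% had the same sign; genes are not independent replicates. The extracellular matrix gene Tgfbi rose from 23.5 ± 8.88 to 384 ± 83.1 CPM in WT (log2 4.13, SE 0.26, edgeR adjusted p = 1.06e-06) and from 38.4 ± 4.76 to 566 ± 53.9 CPM in KO (log2 3.92, SE 0.30, adjusted p = 9.3e-06). Spp1, which encodes osteopontin, had log2 changes of 6.67 in WT and 9.07 in KO, and its call was lost without WT fresh replicates 1 or 2 (highest adjusted p 0.0958) and, in KO, without KO fresh replicate 1 (0.144). The WT value was 7.75 without WT fresh replicate 3 and 5.51 without WT vehicle replicate 2. The KO value was 7.94 without KO vehicle replicate 2. KO fresh replicate 1 had 0 counts, so the 15.93 fitted without KO fresh replicate 2 is no measured size.

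The gene counts depended on single libraries, and so did the 143 shared genes, which numbered 67 without WT fresh replicate 2. Leaving out any 1 of the 6 WT libraries lowered the WT count. It was 139, 85 and 103 without WT fresh replicates 1, 2 and 3, and 122, 153 and 138 without WT vehicle replicates 1, 2 and 3. The KO count was 76 and 488 without KO fresh replicates 1 and 2, and 128, 150 and 135 without KO vehicle replicates 1, 2 and 3. With the sparse library left out of the fit, 440 genes passed in WT and 554 in KO. DESeq2 called 866 and 916 and limma 706 and 542; in KO, limma gave 180 higher and 362 lower. Of the named genes that changed, 30 of 64 in WT and 28 of 68 in KO passed in each fit without 1 library. Unless a library is named, the genes given below are among these.

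**Figure D3:**
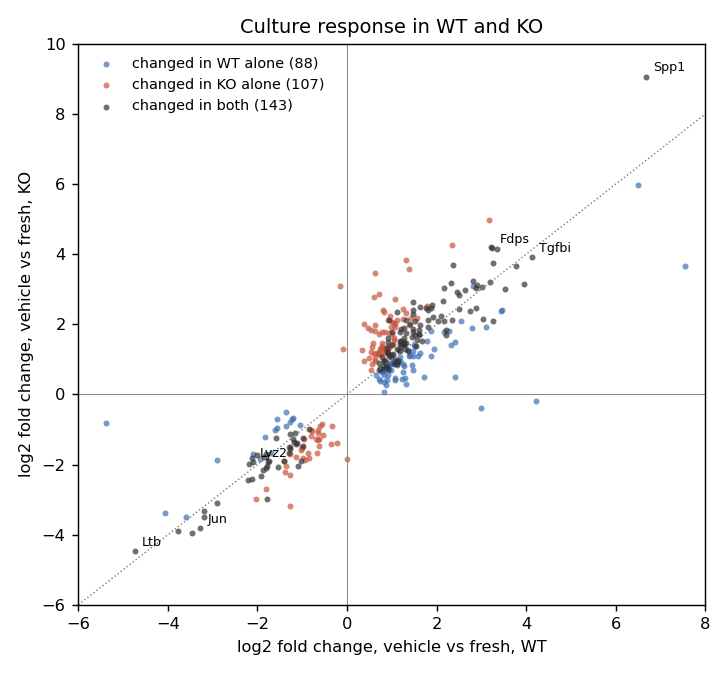
Log2 fold change of vehicle culture against fresh cells in WT (x axis) and KO (y axis) for the 338 genes that changed in either genotype, coloured by where they changed. The axes show 334 of them, and the dotted line marks equal change; 143 genes changed in both genotypes.

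Cholesterol synthesis showed the largest list change. All 30 tested genes of cholesterol synthesis and uptake were above 0 in both genotypes, with medians of 2.19 in WT and 2.30 in KO. Over all genes 16 rose in WT and 15 in KO, and 23 and 24 adjusted over the list alone. Fdps, a synthase of the mevalonate pathway, rose from 93.7 ± 20.2 to 833 ± 79.2 CPM in WT and from 47.3 ± 18.6 to 828 ± 143 CPM in KO, 9.49-fold and 18.1-fold. Sqle, squalene epoxidase, rose by log2 2.45 (SE 0.19) and 2.94 (SE 0.23), and Hmgcs1, which makes the mevalonate precursor HMG-CoA, by 3.27 (SE 0.33) and 3.74 (SE 0.40). The list passed camera in both genotypes, also with an estimated correlation (adjusted p = 6.6e-05 and 9.5e-05).

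Cell cycle genes rose with culture. The S phase list had medians of 1.07 in WT and 1.63 in KO, with 9 and 15 of 44 members higher over all genes and 25 and 37 adjusted over the list alone. The mitosis list had medians of 0.96 and 1.66, with 9 and 12 of 45 members higher and 19 and 36 adjusted over the list alone. Mki67, a marker of cycling cells, rose from 195 ± 54.1 to 520 ± 55.5 CPM in WT and from 101 ± 26.7 to 416 ± 55.8 CPM in KO. Plk1, a mitotic kinase, rose by log2 2.15 (SE 0.32) and 2.66 (SE 0.38). Both lists held with an estimated correlation (adjusted p = 0.014 and 0.0016 for S phase, 0.029 and 0.007 for mitosis). Cdkn1a, which encodes the cell cycle inhibitor p21, rose as well, from 12.9 ± 2.18 to 167 ± 71.1 CPM in WT and from 12.9 ± 1.91 to 158 ± 61.7 CPM in KO. It was the 1 changed member of the senescence list, whose medians were 0.97 and 1.64 (adjusted p = 0.014 and 0.0087 with an estimated correlation). The second median was 1.01 without KO fresh replicate 1. Other members with positive values, Hmgb2 and Lmnb1, are known to be abundant in dividing cells, so the rise of this list cannot be read as senescence.

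Genes of HSC identity fell with culture, with medians of −0.98 in WT and −0.89 in KO. Of 40 members 6 fell in WT and 5 in KO, and 1 rose in each. Adjusted over the list alone 8 and 10 fell. Angpt1, the Tie2 ligand, fell from 427 ± 66.2 to 99.3 ± 19.3 CPM in WT, and from 416 ± 161 to 121 ± 10.6 CPM in KO, where its adjusted p was 0.0563 without KO fresh replicate 2. Txnip, a regulator of thioredoxin and glucose uptake, had log2 changes of −2.90 (SE 0.42) and −3.10 (SE 0.44), and the transcription factor gene Lmo2 −1.12 (SE 0.18) and −1.38 (SE 0.20). The list held with an estimated correlation (adjusted p = 0.014 and 0.007). Cd34, which marks the exit from the most primitive mouse HSC state, rose from 347 ± 55.5 to 732 ± 65.3 CPM in WT and from 257 ± 46.3 to 866 ± 153 CPM in KO. Quiescence-associated genes had medians of −0.58 and −0.85 (adjusted p = 0.39 and 0.16 with an estimated correlation). In WT their call at the preset correlation was lost without WT vehicle replicate 1 (median −0.33, adjusted p = 0.0582).

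Antigen presentation and stress genes also moved. Antigen presentation genes fell, with medians of −0.81 in WT and −1.01 in KO (adjusted p = 0.029 and 0.057 with an estimated correlation). The KO median was −0.48 without KO fresh replicate 1. H2-T23, a class I gene, fell from 916 ± 202 to 232 ± 64.5 CPM in WT and from 1000 ± 135 to 220 ± 19.6 CPM in KO; reads of H2 genes may be shared between near-identical copies. Interferon response genes had medians of −1.24 and −1.07 with no single changed member, and 7 lower in WT adjusted over the list alone (adjusted p = 0.097 and 0.18 with an estimated correlation). Unfolded protein and integrated stress response genes rose, with medians of 0.71 and 0.70 (0.022 and 0.027), the first of which was 0.42 without WT vehicle replicate 3. Among them the lipoprotein receptor gene Vldlr rose from 46.5 ± 7.18 to 501 ± 151 CPM in WT and from 51.8 ± 50.2 to 398 ± 90.3 CPM in KO. The KO log2 change of 3.02 was 4.60 without KO fresh replicate 2 and 2.27 without KO fresh replicate 1. Heat shock genes had medians of 0.50 and 0.49 (0.13 and 0.23).

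Metabolic lists rose at the preset correlation but not with an estimated one. Glycolysis and hypoxia genes had medians of 0.30 in WT and 0.38 in KO (adjusted p = 0.097 and 0.13 with an estimated correlation), with 4 members higher in each. The WT median was 0.18 without WT vehicle replicate 2 and 0.02 without WT vehicle replicate 3. Pkm, pyruvate kinase, rose from 1040 ± 55.3 to 2230 ± 78.3 CPM in WT and from 1130 ± 241 to 2580 ± 111 CPM in KO. Ribosome biogenesis and MYC targets had medians of 0.56 and 0.63 (0.093 and 0.081). Oxidative phosphorylation genes had medians of 0.31 and 0.25 (0.39 and 0.50), the second of which was −0.10 without KO fresh replicate 2 (camera adjusted p = 0.339) and 0.67 without KO fresh replicate 1. The first was 0.53 without WT fresh replicate 1. Reactive oxygen and glutathione defence genes passed in WT with a median of 0.35 (0.13), or 0.18 without WT vehicle replicate 3. Among them Gclm, a subunit of the glutathione-synthesizing ligase, rose by log2 2.21 (SE 0.18, edgeR adjusted p = 1.05e-05). In KO Gclm rose by 1.70 (SE 0.21, adjusted p = 0.000556). The glutathione defence list did not pass in KO. Its list score (the mean log2 expression of the members relative to the mean over all libraries) rose there from 0.01 ± 0.18 to 0.25 ± 0.11. In WT that score rose from −0.30 ± 0.10 to −0.07 ± 0.29.

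Early response and lineage genes gave mixed values. Jun, an immediate early transcription factor, fell from 681 ± 412 to 66.1 ± 32.1 CPM in WT and from 1020 ± 357 to 70.3 ± 20.1 CPM in KO. Socs3, a cytokine-induced inhibitor of the same list, rose in WT by log2 3.05 (SE 0.40). The immediate early list passed in KO with a median of −0.24 (adjusted p = 0.30 with an estimated correlation; lost without KO fresh replicate 1 or KO vehicle replicate 3, highest adjusted p 0.12; median −0.46 without KO vehicle replicate 2). In WT the immediate early list did not pass, though its list score fell from 0.24 ± 0.50 to −0.29 ± 0.56, and in KO from 0.73 ± 0.11 to 0.04 ± 0.47. Lyz2, lysozyme of myeloid cells, fell by 2.11 in WT and 1.94 in KO on the log2 scale, and Car2, a carbonic anhydrase of erythroid cells, fell by 1.29 and 1.68. Granulocyte and monocyte genes passed in KO with a median of −1.29 (0.38). Without KO vehicle replicate 3 it was −0.85 (0.0596 at the preset correlation) and without KO fresh replicate 2 it was 0. In WT this list did not pass, though its list score fell from 0.62 ± 0.25 to −0.24 ± 0.97, and in KO from 1.05 ± 0.97 to −0.09 ± 0.64. Megakaryocyte and platelet genes passed in KO with −0.52 (0.44; lost without KO fresh replicate 2 or KO vehicle replicate 1, highest 0.195; median −0.81 without KO vehicle replicate 2). In WT the megakaryocyte and platelet list did not pass, though its list score fell from 0.68 ± 0.03 to −0.27 ± 0.45. In KO that score fell from 0.52 ± 0.41 to −0.05 ± 0.12. Within that list Thbs1, thrombospondin, had 0 counts in each WT vehicle library, at least 413-fold lower than 86.8 ± 31.0 CPM in fresh WT. The p53 target list passed in WT with 0.48 (0.39), and was lost without WT fresh replicates 1 or 3 or WT vehicle replicates 2 or 3 (highest 0.0994; median 0.31 without WT fresh replicate 1). In KO this list did not pass, though its list score rose from −0.10 ± 0.26 to 0.59 ± 0.28. In WT that score rose from −0.39 ± 0.20 to −0.05 ± 0.52.

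Cytosolic ribosomal protein genes had medians of −0.14 in WT and −0.67 in KO with culture (camera adjusted p = 0.0373 and 1.75e-14; 0.86 and 0.38 with an estimated correlation). The KO median was 0.13 without KO fresh replicate 1 (0.165) and −1.13 without KO fresh replicate 2. The WT median was −0.03 without WT fresh replicate 1 (0.952), with a test direction opposite to that of all libraries, and the WT call was also lost without WT vehicle replicates 1 or 2. The WT median was −0.06 without WT vehicle replicate 1, −0.29 without WT fresh replicate 3 and −0.35 without WT vehicle replicate 3.

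No list passed in vehicle against fresh cells among the remaining groups. Medians in WT and KO were −0.81 and −0.39 for aging genes, −0.12 and −0.71 for erythroid genes, 0.05 and 0.00 for mast cell and basophil genes, and −0.79 and −0.39 for lymphoid priming genes. They were −0.90 and −1.33 for endothelial and stromal genes, 0.02 and 0.18 for NF-kB and inflammatory genes, and −0.10 and −0.18 for selectins, ligands and adhesion genes. Lysosome and autophagy genes had 0.04 and 0.02, epigenetic and splicing regulators −0.05 and −0.32, lncRNAs and imprinted genes −0.11 and −0.15, and genes of distal chromosome 1 near Selp −0.10 and −0.28. The mean had the sign opposite to the median for lysosome and autophagy genes in both genotypes and for lncRNAs and imprinted genes in WT.

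**Figure D4:**
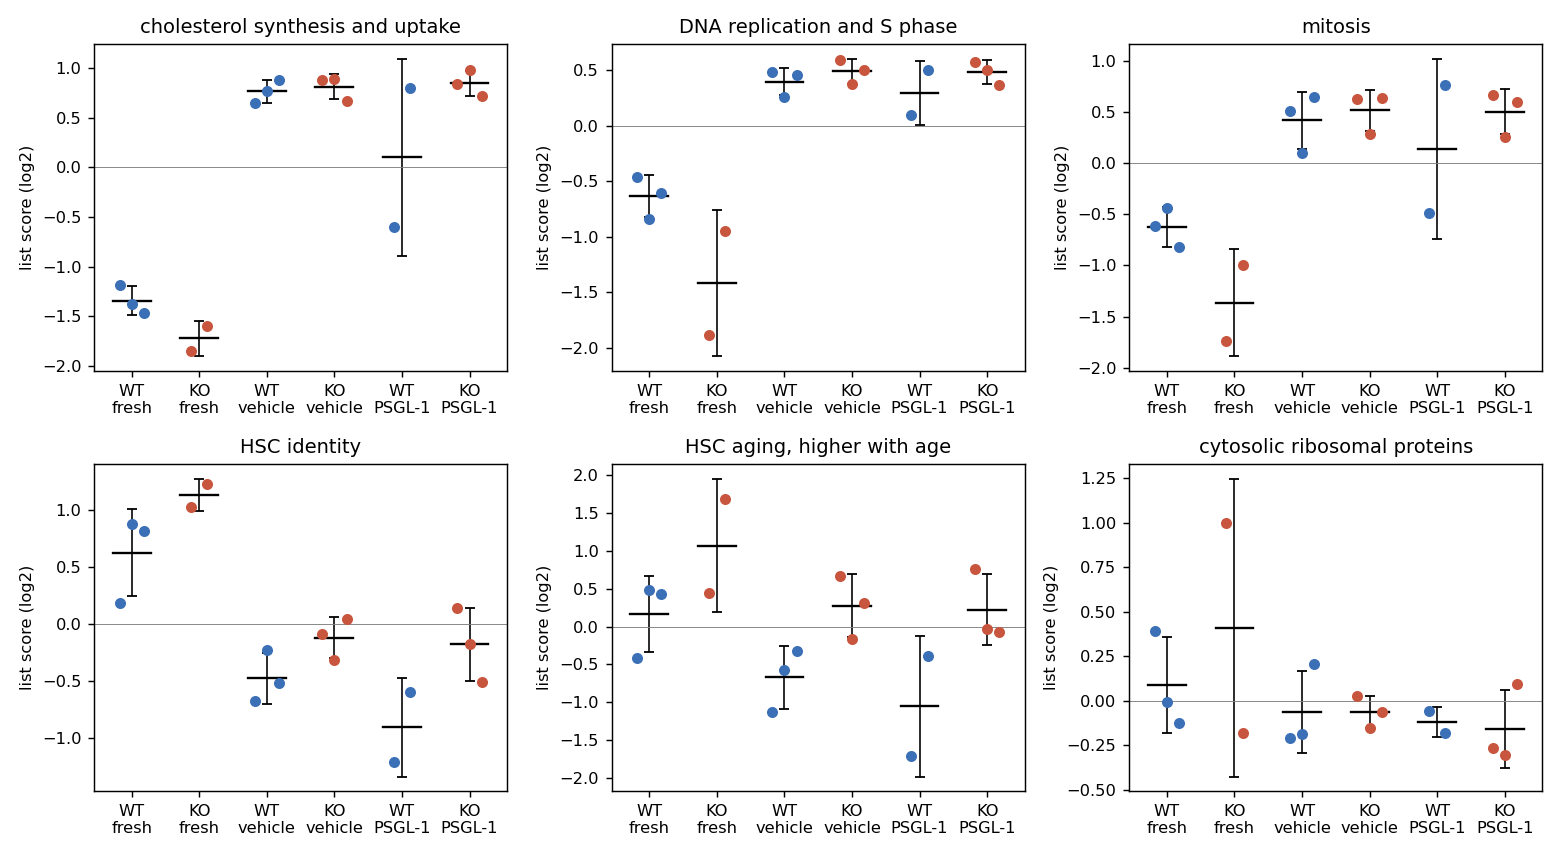
Scores of 6 gene lists per library (mean log2 expression of the members relative to the mean over all libraries), by group. Points are libraries, black lines are means and bars are 1 SD; cholesterol, S phase and mitosis scores lie higher in vehicle cultures than in fresh cells, and HSC identity scores lower.

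After vehicle culture the genotypes differed in 1 gene, Eno1b, at 118 ± 4.55 CPM in KO and 1.40 ± 0.316 CPM in WT (log2 6.38, SE 0.40, edgeR adjusted p = 8.03e-07). Aging genes again lay higher in KO, with 36 of 46 above 0 and a median of 0.58 (camera adjusted p = 0.000107; adjusted p = 0.68 with an estimated correlation). The median was 0.26 without KO vehicle replicate 1. Clu was at 278 ± 76.3 and 84.5 ± 32.5 CPM and Vwf at 148 ± 52.2 and 58.2 ± 13.1 CPM, and both were higher adjusted over the list alone. S phase and mitosis genes had medians of 0.03 and 0.05 and passed no test here. At an unadjusted p under 0.05 there were 400 genes. DESeq2 called 111 and limma 3, and edgeR 8 without WT vehicle replicate 3 and 2 with the sparse library left out of the fit. Fresh and vehicle fold changes between genotypes correlated across 10676 genes with r = 0.14, and Eno1b was the 1 shared call.

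After PSGL-1, Eno1b was again the 1 gene that differed, at 120 ± 4.01 CPM in KO and 1.46 ± 0.0758 CPM in WT (log2 6.34, SE 0.48, edgeR adjusted p = 1.16e-05). Ribosomal protein genes had a median of −0.10 (camera adjusted p = 0.00759; 0.91 with an estimated correlation). It became 0.03 without WT PSGL-1 replicate 1 (0.787), and the call was also lost without KO PSGL-1 replicates 1 or 2, with medians of −0.04 in both. Without KO PSGL-1 replicate 3 the median was −0.24. Aging genes had a median of 0.78 and did not pass camera (adjusted p = 0.358) or fry with a direction (0.397). They passed fry in either direction (0.0115), a form of the test given here for this list alone. Neo1 was the 1 member higher adjusted over the list alone (0.0493). The 2 WT PSGL-1 libraries, 1 of them sparse, had aging list scores of −1.71 and −0.39, against 0.22 ± 0.47 in KO. At an unadjusted p under 0.05 there were 820 genes. DESeq2 called 300 and limma 0, and an edgeR fit of the 2 groups compared alone called 0, so Eno1b did not pass there. Without WT PSGL-1 replicate 2, which leaves the sparse library alone in its group, edgeR called 2979.

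PSGL-1 itself gave no gene past the threshold in either genotype. In WT, edgeR called 0 of 14124 genes, with 803 at an unadjusted p under 0.05 where 706 were expected. In KO it called 0, with 198 at that level. The difference of the PSGL-1 response between genotypes gave 0, with 611. Limma called 0 genes in each of these comparisons. In KO and for the difference, fewer genes than the 706 expected lay under 0.05 in edgeR. The same held for KO against WT in fresh cells (401) and after vehicle (400). These p-values thus lay higher than expected without any change, so a count of 0 does not show that nothing changed. DESeq2 called 258 genes in WT, 71 higher and 187 lower, 42 in KO and 132 for the difference. Without WT PSGL-1 replicate 2 the edgeR counts were 2955 in WT and 2370 for the difference, and without WT vehicle replicate 3 they were 6 and 3.

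No gene group passed its test with PSGL-1. None of the 30 lists passed camera, with smallest adjusted p of 0.699 in WT, 0.469 in KO and 0.579 for the difference. HSC identity genes had medians of −0.04 in WT and −0.04 in KO, and aging genes 0.08 and −0.07. S phase genes had −0.13 and −0.01, and mitosis genes −0.02 and 0.03. NF-kB and inflammatory genes had −0.02 in WT and 0.32 in KO. Erythroid genes had −0.83 in WT, with 20 of 25 below 0, and 0 in KO, and granulocyte and monocyte genes −0.68, with 22 of 34 below 0, and 0. In WT, lymphoid priming genes had −0.31, p53 targets 0.30, selectins, ligands and adhesion genes −0.27 and quiescence-associated genes −0.27. The 2 WT PSGL-1 libraries lay far apart in these lists. The sparse replicate 1 and replicate 2 had list scores of −2.16 and 0.35 for erythroid genes, against −0.08 ± 1.51 after vehicle, and −2.50 and −0.12 for granulocyte and monocyte genes, against −0.24 ± 0.97. For selectins, ligands and adhesion genes they were −2.38 and 0.25, against 0.03 ± 0.29, and for quiescence-associated genes −2.88 and 0.05, against −0.11 ± 0.40. Only the sparse library lay below the vehicle means of these 4 lists. For HSC identity, aging, lymphoid priming, S phase, mitosis and NF-kB genes in WT, and for HSC identity, aging, S phase and mitosis genes in KO, the median, the mean and camera's direction did not all have 1 sign. Camera compares a list with the other genes tested, and the median over all genes was −0.11 in WT. Selp was at 162 ± 29.1 CPM with PSGL-1 and 75.2 ± 58.0 with vehicle in WT, a log2 difference of 1.08 (SE 1.37, edgeR adjusted p = 0.912). Across 10676 genes the PSGL-1 fold changes in WT and KO correlated with r = 0.0204, and 51.3% had the same sign. In the simulations, 26% of 4-fold changes were recovered in WT and 34% in KO, and 0% and 8% of 2-fold changes. Changed genes there had means of at least 5 CPM and no simulated library was sparse, so recovery may be lower in these data.

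Genes near Selp were examined because a knockout can carry flanking DNA of another strain. Within 20 Mb of Selp 230 genes were tested, and none passed edgeR's test in any condition (Fisher's exact p = 1 in each). With only 1 gene called in each condition, Eno1b on chromosome 18, this comparison has too few calls to decide about flanking DNA. A cutoff not fixed beforehand, an unadjusted p under 0.01, gave 6 of 230 near Selp after vehicle culture, against 53 of 13878 elsewhere (exact p = 0.000385). In fresh cells there was 1 (exact p = 1), and after PSGL-1 there were 4 (exact p = 0.301). DESeq2 called 1, 5 and 8 genes there in fresh cells, after vehicle and after PSGL-1 (exact p = 1, 0.0312 and 0.151). The edgeR count was 2 in fresh cells without KO fresh replicate 2 (0.403), 1 after vehicle without WT vehicle replicate 3 (0.123), and 53 after PSGL-1 without WT PSGL-1 replicate 2 (0.752).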

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

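The test of whether culture acted differently in KO and WT was chosen after the culture response had been seen, while the tests of the fresh cell cycle lists were written before their values. For 5 lists the culture response differed between KO and WT in camera at the preset correlation. None of them passed with an estimated correlation, where the adjusted p were 0.55 for S phase, mitosis, cholesterol and immediate early genes and 0.98 for ribosomal protein genes, or with fry. Values are medians over the members of each gene's KO minus WT difference in culture response. The median was 0.614 for S phase genes (camera adjusted p = 3.81e-10) and 0.575 for mitosis genes (2.29e-10), and both passed at the preset correlation in each of the 11 fits without 1 library. Without KO fresh replicate 2 these were 0.955 and 1.05, and S phase had 0.309 without KO fresh replicate 1. The median was 0.407 for cholesterol genes (0.0117), lost without KO vehicle replicate 2, WT fresh replicate 1 or WT vehicle replicate 3 (highest 0.177; median 0.245 without KO vehicle replicate 2). Immediate early genes had −0.528 with a mean of 0.465 (0.0117), lost without KO fresh replicate 1, KO vehicle replicate 3, WT fresh replicate 1 or WT vehicle replicate 2 (highest 0.327, with a median of −0.337). Ribosomal protein genes had −0.46 (2.04e-11), which turned to 0.283 without KO fresh replicate 1 and was −0.906 without KO fresh replicate 2.

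In edgeR 0 single genes differed in their culture response, with 353 at an unadjusted p under 0.05. DESeq2 called 73 and limma 0, and edgeR 31 without KO fresh replicate 2, 1 without WT fresh replicate 2 and 2 without WT vehicle replicate 3.

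The S phase and mitosis difference lay in the fresh cells, where both lists were lower in KO, while after vehicle the median KO against WT fold changes were 0.03 and 0.05. The condition set beforehand against 1 library as the source of the fresh difference was met. Over the 5 fits without 1 fresh library the highest camera adjusted p of the 2 lists was 0.000161. The medians ran from −0.698 to −0.311 for S phase and from −1.17 to −0.467 for mitosis. This test cannot exclude such a source, since the ribosomal protein list passed it in opposite directions with and without KO fresh replicate 1. The fresh list scores of both KO libraries, −1.882 and −0.95 for S phase, lay below the WT range of −0.838 to −0.458. For mitosis they were −1.736 and −0.996, against −0.823 to −0.434. The lower direction thus did not rest on 1 library, while the size changed with the library left out. For transcripts lost from sparse libraries, the 79 of 89 members with a mean of at least 50 CPM over all libraries were examined. Their median was −0.49 (interval over members −0.68 to −0.41, without the spread between libraries), which met the condition set beforehand against that source. Of them, 78 had counts in all 5 fresh libraries, so complete loss does not account for their lower values. The cut kept most members of both lists, so it cannot exclude partial loss. The difference rests on 2 KO libraries and did not pass with an estimated correlation. The cell cycle state of the cells was not measured here, so no biological explanation was tested.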

How the results depend on the processing

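The limma fits, the fits without the sparse library, DESeq2 without a WT PSGL-1 library, the culture response shared between genotypes, the culture by genotype difference and the mean over 3 conditions were chosen after the data were seen. RLE size factors, the stricter filter and the 2-fold minimum left each of the 10 counts of changed genes within 1.5 times. Where a group was left with 1 library, that library was assumed to vary like the other groups. The cause was not tested for any change below, other than that fewer libraries were used.

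DESeq2 called 99, 111 and 300 genes for KO against WT in fresh cells, after vehicle and after PSGL-1, 258 and 42 with PSGL-1 in WT and KO, 132 for their difference, 866 and 916 with culture in WT and KO, 73 for the culture difference and 266 for the mean over conditions. It shared 7 calls between the PSGL-1 responses, 13 between fresh and vehicle genotype differences and 427 between culture responses. It called 1, 5 and 8 genes near Selp, and gave Selp −5.89 in fresh cells and −4.95 after PSGL-1. DESeq2 without WT PSGL-1 replicate 1 gave 121 genes with PSGL-1 in WT, 123 for KO against WT after PSGL-1 and 95 for the difference, and without replicate 2 it gave 4937, 5057 and 4135. Limma gave 7, 3 and 0 between genotypes in the 3 conditions and 706 and 542 with culture. With the sparse library out of the fit there were 3 and 2 genes between genotypes in fresh cells and after vehicle, 440 and 554 with culture, and 271 and 2 shared. No filter gave 3 in fresh cells, and fits of the groups compared alone gave 2 there and 0 after PSGL-1.

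Leaving out 1 library gave 1–83, 1–8 and 1–2979 genes between genotypes in fresh cells, after vehicle and after PSGL-1, and 4–2272 for their mean. It gave 0–2955 with PSGL-1 in WT, 0–0 in KO and 0–2370 for the difference, 85–153 and 76–488 with culture in WT and KO, and 0–31 for the culture difference. Shared calls were 0–0 for PSGL-1, 1–1 for genotype and 67–146 for culture. Calls near Selp were 0–2, 0–1 and 0–53. Selp was at most −4.87 in fresh cells, where the lowest value, −13.02 without KO fresh replicate 2, is set by the fit because the KO library left has 0 counts. It was −3.92 to −2.52 after vehicle and −5.90 to −4.37 after PSGL-1. Over all called lists and these fits, 369 list calls were kept, 60 were lost with their direction kept and 7 turned direction.

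Values whose sign or test direction turned without 1 library ranged as follows. For the glutathione defence list in fresh cells and the ribosomal protein list with culture in WT, camera's direction turned while the median kept its sign. For KO against WT in fresh cells: Gpx4 −0.25 to 0.85, Rpl13 −0.11 to 1.02, the glutathione defence list 0.0343 to 0.39 and the ribosomal protein list −0.316 to 0.879. The ribosomal protein list ranged from −0.235 to 0.0286 after PSGL-1, −1.13 to 0.127 with culture in KO, −0.352 to −0.025 in WT and −0.906 to 0.283 for the culture difference. There Rpl13 ranged from −1.04 to 0.07 and Rpl35 from −1.14 to 0.15. With culture in KO, the oxidative phosphorylation list ranged from −0.10 to 0.672. Mpo had 0 counts in all KO vehicle libraries and in KO fresh replicate 1, so its fitted values, −14.79 to 0, measure no change of sign. Selp ranged from −1.46 to 0.07 with PSGL-1 in KO and −0.59 to 0.97 with culture in WT. Selplg, which passed no test, ranged from −0.35 to 0.51 between genotypes after PSGL-1, −0.31 to 0.10 after vehicle and −0.03 to 0.27 in the mean. It ranged from −0.34 to 0.10 and −0.73 to 0.14 with PSGL-1 in KO and WT, −0.59 to 0.28 for their difference and −0.23 to 0.41 with culture in KO, where DESeq2 and RLE gave −0.03 and no filter −0.01.

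Whether replicate numbers pair the libraries was left open, since the share of matches expected by chance was not computed. By replicate number 9 of 16 correlated best with their own number, at mean r of 0.02 within and −0.011 across numbers. By library number 7 of 16 did. Deviations within a group of 2 libraries mirror each other, so these matches are not independent. With the replicate block, by title or by library number, genes changed with culture numbered 198 and 203 in WT and 206 and 222 in KO, shared 114 and 122, and the mean contrast gave 4. Selp was −5.46 and −6.55 in fresh cells, −3.09 and −2.76 after vehicle and −5.42 and −5.22 after PSGL-1. Selplg after PSGL-1 was 0.09 and 0.03. All other counts were equal to those without a replicate block. Under these forms 19 and 18 named genes lost their call, 2 gained one under each, and 3 and 4 lists lost theirs.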

Other observations

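The KO against WT difference averaged over the 3 conditions, and the tests of Eno1b and of gene positions, were chosen after the results were seen. In that average 5 genes passed edgeR's test, 3 higher and 2 lower in KO. Eno1b was at 108 ± 20.9 CPM in KO and 1.42 ± 0.175 in WT, and Trim12a, a TRIM family gene, at 35.6 ± 20.4 in KO (adjusted p = 0.00204). In WT it had 0 counts in 6 of 8 libraries and at most 5 counts in the others, so no fold is given. Trim12c, a gene of the same family chosen after its values were seen, averaged 20.7 ± 14.1 CPM in KO and 46.6 ± 21.7 in WT. Reads may be shared between these genes, so a switch of Trim12a itself is uncertain. Clu was at 241 ± 68.8 and 74.6 ± 37.6 CPM (log2 1.67, SE 0.22, adjusted p = 0.00667). Lower in KO were Wdfy1, a gene of endosomal signalling, at 38.0 ± 13.2 and 141 ± 48.7 CPM (log2 −1.85, SE 0.30, adjusted p = 0.0434), and Gas5, a growth arrest lncRNA, at 111 ± 40.7 and 297 ± 66.0 CPM (log2 −1.38, SE 0.18, adjusted p = 0.00524). Wdfy1 lost its call in 11 of the 16 fits without 1 library, with the highest adjusted p, 0.224, without KO fresh replicate 1. The count of 5 became 2272 without WT PSGL-1 replicate 2, 50 without KO fresh replicate 2 and 10 without WT vehicle replicate 3, and DESeq2 called 266.

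Of 10676 genes, 7 separated all KO from all WT libraries, where 1.66 would by chance. They were Selp, Eno1b, Trim12a, Wdfy1, Apbb2, Gm5801 and Nnt. Nnt, chosen after its value was seen, was at 59.8 ± 21.9 CPM in KO and 165 ± 79.8 in WT (log2 −1.55, adjusted p = 0.0889).

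DNA of another strain kept around Selp would place the differing genes near it. Of Eno1b, Trim12a, Clu and Wdfy1, 0 lie within 20 Mb of Selp, which argues against that source for them. Gas5 lies 3.08 Mb from Selp, so for Gas5 the loss of P-selectin and flanking DNA cannot be told apart. A strain difference elsewhere in the genome may have set the 4 genes apart, since they lie on 4 chromosomes; Nnt is known to carry a deletion in the substrain C57BL/6J. The loss of P-selectin would allow the same positions, and the strains are not given in the sources used here.

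Eno1b was 7.73 ± 0.654% of the Eno1 and Eno1b counts in KO and 0.0999 ± 0.0262% in WT. Eno1 reads counted for Eno1b could produce such a share, for instance through a sequence variant. Over the 6 cultured KO libraries the levels of both genes had r = 0.545 (exact permutation p = 0.272), and r = −0.281 without the 2 libraries farthest out. The fresh KO libraries, left out there, had less of both, with Eno1 at 829 and 887 CPM and Eno1b at 80.7 and 69.8. Cultured KO cells averaged 1420 and 1490 CPM of Eno1 after vehicle and PSGL-1, and 118 and 120 of Eno1b. Between fresh and cultured KO cells Eno1b thus moved with Eno1, and the explanation remains open.

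DESeq2 called 258 genes with PSGL-1 in WT where edgeR called 0, with 803 at an unadjusted p under 0.05, and limma 0. Before the values were seen, it was set that 1 sparse library makes the calls if DESeq2 without WT PSGL-1 replicate 1 called less than 1 gene for every 3 that it called without WT PSGL-1 replicate 2. The counts were 121 and 4937, so that condition was met. Further values were weighed only afterwards: 91 of the 258 genes were also called without replicate 1 and 239 without replicate 2. Of the 187 lower genes, 170 had 0 counts in replicate 1, 140 in replicate 2 and 140 in both. For these reasons the sparse library and a response to PSGL-1 cannot be told apart as sources of all 258 calls.

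The 6 libraries of a comparison of 3 and 3 can be split in 10 ways, too few for a share under 0.05. For KO against WT after vehicle, 1 of 10 splits gave as many genes as the real split, itself, with 1 gene and at most 0 in the others. For vehicle against fresh WT this was 1 of 10, with 231 genes and at most 0. For PSGL-1 against vehicle in KO it was 10 of 10, with 0 genes in each. The real split gave 0 genes there, so no split could give fewer, and this count decides nothing.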
